A study of Homo sapiens with 12 samples.

How the data were processed

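RNA from human peripheral blood monocytes was measured on 12 oligonucleotide arrays, 3 for each of 4 groups. Cells were cultured for 2 days with M-CSF (control), or the same and stimulated with IFN-alpha for 3 hours (IFN-alpha). Others were cultured for 2 days with M-CSF and IFN-gamma (IFN-gamma), or the same and stimulated with IFN-alpha for 3 hours (IFN-gamma then IFN-alpha). Whether the 3 hours fell within the 2 days is not given in the sample labels. The deposited values are linear intensity signals, 1 per probe set and array, as the authors gave them. The method that summarised probes into signals, the background correction and the scaling are not given in the sources used here. Leaving out 2% of the values at each end, the mean was 250.1 on every array, so the values were used as deposited without another scaling. They ranged from 0.2 to 27592.4 with a median of 67.6, and 0 were missing.

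The table held 12625 probe sets, of which 10961 had 1 gene symbol, 545 had several and 1119 had none in the probe table used here. The 67 control probe sets were left out, and probe sets with several or no symbols were tested but not named. Of the 8 genes chosen in advance to be given in any case, 1 had no named probe set here. Signals were analysed as log2(signal + 6), where 6 is the rounded 10th percentile of all values. A probe set was tested when it reached the 40th percentile of the array on at least 3 arrays, which left 8501. Dim signals limit the lower end: changes of probe sets near the pseudocount are compressed.

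A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend (8 residual degrees of freedom, or 6 with replicate as a block). The 5 comparisons were IFN-alpha minus control, IFN-gamma then IFN-alpha minus IFN-gamma, IFN-gamma minus control, IFN-gamma then IFN-alpha minus IFN-alpha, and the difference of the first 2 (the interaction). P values were adjusted by the Benjamini-Hochberg method over all probe sets of a comparison, and a probe set was called at an adjusted p under 0.05. The p-values set each difference against the spread between these samples. Whether the samples come from different donors is not given, so the p-values cannot be taken to extend to other donors or cultures. With 3 arrays per group an exact test on ranks reaches no lower than p = 0.1, so the moderated tests carry the calls, and the number of arrays limits the precision of every change.

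Gene lists were written before the data were examined: 14 of pathways and 7 of cell types, with 330 members, of which 282 had a named probe set. Some genes were in more than 1 list, so shifts of these lists are not independent. TNFSF10 and XAF1 were antiviral and apoptosis members, FAS and CASP1 IFN-gamma-inducible and apoptosis members, and TAP1 and PSMB9 IFN-gamma-inducible and class I members. Lists with at least 3 tested members, 20 in all, were tested with camera in limma at a preset correlation of 0.01 against the other genes, with 1 probe set for each of 6017 genes. A test with the correlation estimated from the data, and fry, which tests a list against no change, were alternatives. With an estimated correlation and all arrays, the calls of the antiviral list in the 2 IFN-alpha comparisons held (adjusted p = 0.012 and 0.0141), and those of the other lists did not. Members were also counted with p adjusted over the list alone.

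Genes were named by a rule fixed before the data were examined: in each comparison, the 12 largest rises and the 12 largest falls among called probe sets with 1 symbol and the same direction in all 3 sets, 1 per gene. Where fewer than 5 passed, the genes with the 10 smallest p were given as values. Up to 4 called members of each list, and CXCL9, CXCL10, IRF1, MX1, ISG15, SOCS1 and SYK in any case, were added. 1 gene was left unnamed to keep the people who gave the samples unidentified. The second probe sets of named and listed genes, 126 in all, made 0 calls in the opposite direction. Of those whose gene was called, 27 of 37 were called in the same direction for IFN-alpha minus control and 23 of 34 after IFN-gamma culture, so the size of a change depends on the probe set.

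Arrays were put into 3 sets by a label they share, and the grouping was checked on the values. After the group means were removed, the 18 pairs within a set correlated at 0.113 to 0.442 and pairs across sets and groups at -0.316 to 0.052, and each of the 12 arrays had its closest partner in its own set. Arrays of the same group correlated at 0.913 to 0.942 in level. What a set stands for (1 donor or 1 day of work) is not given in the sources used here. The unblocked model was kept because it was fixed in advance, with replicate as a block as an alternative. It leaves the likeness of arrays within a set unused. For IFN-alpha minus control it made 775 calls, against 1338 with the block.

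The alternatives were a pseudocount of 1 or of 17 (the 25th percentile), quantile normalisation, scaling to the 75th percentile, no filter, a filter at the 60th percentile, no intensity trend, a fit of the compared groups alone, a cut at 2-fold, 1 probe set per gene, replicate as a block, and leaving out each array in turn. The block with control replicate 2 left out was added after the data were seen. Every analysis used all 12 arrays unless stated. The steps were tested on simulated data of 8501 probe sets. There 84.8% of the changes of size 2 (log2) and 25.4% of size 1 were recovered for IFN-alpha minus control. For the interaction these shares were 43.9% and 9.0%, and each of these comparisons had 3 false calls. The simulated noise was independent for each probe set and array, without differences between sets or correlated genes. These shares describe that setting and may differ in the real data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.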

Results

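Gene expression was measured in human peripheral blood monocytes cultured for 2 days with macrophage colony-stimulating factor (M-CSF, the growth factor that keeps monocytes alive and drives them towards macrophages). Interferon-gamma (IFN-gamma, the type II interferon made by T and NK cells) was either present in the culture or absent. Interferon-alpha (IFN-alpha, a type I interferon made in antiviral responses) was either given for 3 hours or withheld. The 4 resulting groups are called control, IFN-alpha, IFN-gamma, and IFN-gamma then IFN-alpha, with 3 arrays each and 12 in all. The arrays fell into 3 sets of 4, each set with 1 array of every group, and the sets are numbered replicate 1 to 3. Each array gave 1 linear signal for each of 12625 probe sets, with a median of 52.2 to 76.8 per array and a highest value of 27592. Signals are given as mean ± SD (n = 3 arrays), changes are log2 values as first group minus second, and the number of arrays limits the precision.

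The first comparison asked what IFN-alpha changed in cells cultured without IFN-gamma. RSAD2, which encodes the antiviral enzyme viperin, rose from 13.3 ± 0.551 in control cells to 7765 ± 2492 after IFN-alpha, a change of 8.60 (SE 0.37, adjusted p = 5.05e-08). The chemokine genes CXCL10 (8.19), CCL8 (8.16), CXCL11 (6.49) and CXCL9 (5.35) also rose, CXCL10 from 60.1 ± 98.1 to 7503 ± 1858. The antiviral genes IFIT2 (7.38), IFIT1 (6.28), IFIT3 (6.09), OASL (5.77) and IFITM1 (5.02) rose, IFIT1 from 162 ± 85.1 to 11940 ± 2930. SOCS1, an inhibitor of JAK kinases that limits cytokine signalling, rose from 21.1 ± 20.9 to 1540 ± 363 (6.07, adjusted p = 2.77e-06), and ENPP2, which encodes the lysophospholipase autotaxin, rose by 5.18. A second probe set of SOCS1 rose by 1.52 without passing the threshold (adjusted p = 0.113), and of 2 further probe sets of ENPP2 1 rose (5.04) and 1 did not (-0.20, adjusted p = 0.883). Leaving out control replicate 2 raised several of these log2 changes, to 9.61 for CXCL10, 9.04 for CCL8, 8.21 for IFIT2, 6.94 for IFIT3, 6.65 for SOCS1 and 5.93 for ENPP2.

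Among the genes that fell after IFN-alpha, CXCR4, the receptor for the chemokine CXCL12, went from 1959 ± 931 to 120 ± 18.3, a change of -3.88 (SE 0.50, adjusted p = 0.000266). FRAT2, which binds the kinase GSK-3, measured 316 ± 32.4 in control cells and fell (-4.29, adjusted p = 0.000532). RGS2, a regulator of G protein signalling, fell by 3.64, as did BTG1, an antiproliferative gene, and the MAP kinase phosphatase genes DUSP7 (-3.45) and DUSP10 (-3.24) fell. MYCL (-3.46), FAM53B (-3.00) and IRAK3 (-2.76), an inhibitor of Toll-like receptor signalling, also fell. The neutrophil chemokine genes CXCL8 (-3.43, adjusted p = 0.046) and CXCL3 (-2.75, adjusted p = 0.00375) fell, and so did DDIT4 (-2.68, adjusted p = 0.0468), an inhibitor of mTOR signalling. Second probe sets of DUSP7 (-0.44, adjusted p = 0.725), MYCL (-1.53, adjusted p = 0.0596) and CXCL8 (-2.36, adjusted p = 0.0561) did not pass the threshold. The calls of CXCL8 and DDIT4 ended when any of 7 and 8 of the 12 arrays was left out, with an adjusted p of 0.169 without control replicate 3 for CXCL8 and 0.191 without control replicate 1 for DDIT4. Quantile normalisation (0.0687 and 0.0682) and 75th percentile scaling (0.066 and 0.0677) ended both calls, no filter (0.0555) and no intensity trend (0.0733) that of CXCL8, and a pseudocount of 1 (0.0737) that of DDIT4. That of IRAK3 ended without control replicate 3 (adjusted p = 0.0564).

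**Figure D1:**
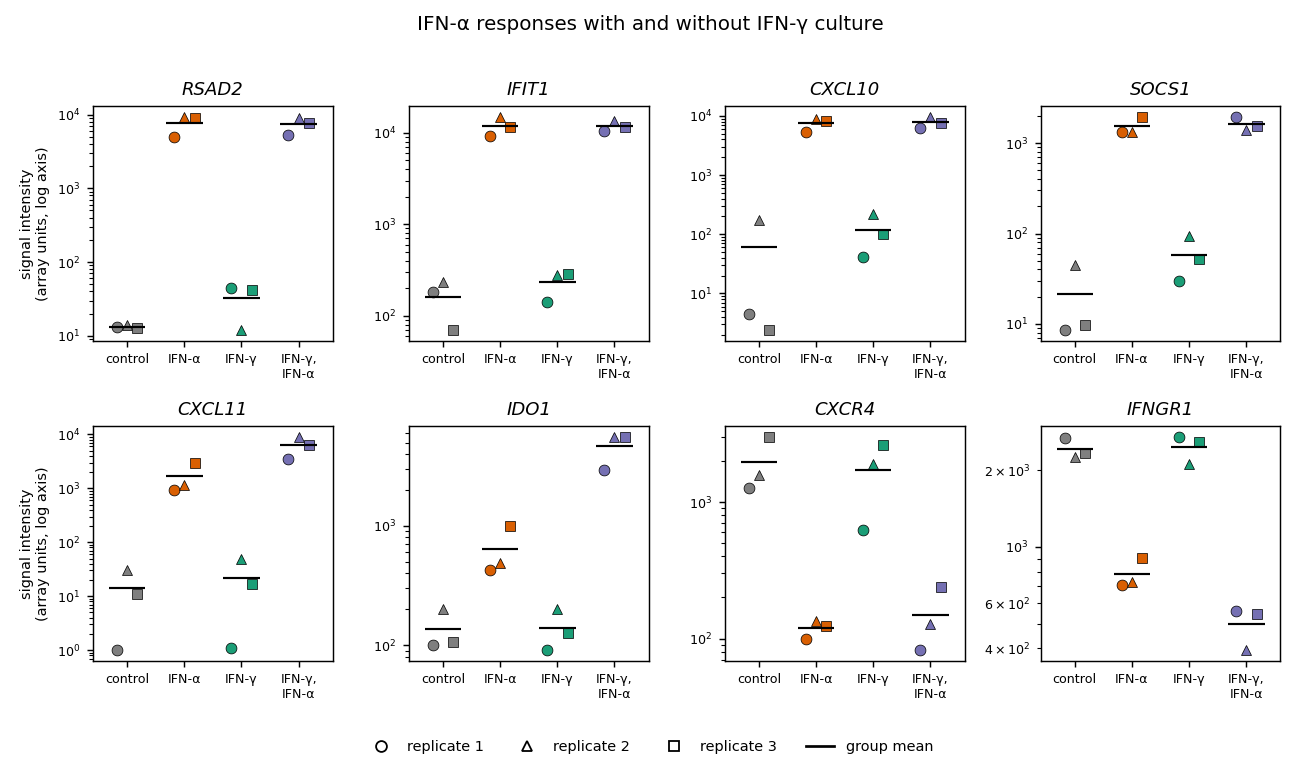
Signal of 8 genes on each of the 12 arrays (log axis), by group, with a bar at each group mean. RSAD2, IFIT1, CXCL10 and SOCS1 reached like levels after IFN-alpha in both cultures, IDO1 stood at 636 in the IFN-alpha group and 4711 in the IFN-gamma then IFN-alpha group, and CXCR4 and IFNGR1 were lower after IFN-alpha in both.

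Of the antiviral interferon-stimulated genes fixed as a list, 28 of 33 measured members rose, 0 fell and 5 did not pass the threshold, with 31 rising when adjusted over the list alone. The list was shifted upwards against the other genes (median change 3.27, adjusted p = 6.23e-54 by camera), and MX1 (4.96, to 8642 ± 1388) and ISG15 (4.58, to 12440 ± 2845) were among its members. Of 21 IFN-gamma-inducible genes, 13 rose and 0 fell, or 16 adjusted over the list alone (median 2.32, adjusted p = 1.8e-17, adjusted p = 0.132 with an estimated correlation). The median was 3.32 without control replicate 2, with 16 rising, and the adjusted p with an estimated correlation was 0.018. That array was singled out because it carried the profile of IFN-gamma culture, as described for the third comparison. Larger changes and lower p values of interferon-responsive lists without it are therefore partly fixed by that choice and are no independent test. Besides the chemokine genes and SOCS1, that list held the transcription factor gene IRF1, which rose from 603 ± 672 to 2175 ± 247 (2.43, adjusted p = 0.0114, or 3.32 without control replicate 2). Of 17 apoptosis genes 9 rose, or 10 with 1 falling adjusted over the list alone, among them the death ligand gene TNFSF10 (4.06, or 5.27 without control replicate 2), XAF1 (3.98), CASP5 (3.00) and the death receptor gene FAS (2.73). TNFSF10 and XAF1 were also members of the antiviral list, and FAS of the IFN-gamma-inducible list. The apoptosis list was shifted upwards (median 1.09, adjusted p = 3.38e-08, adjusted p = 0.0719 with an estimated correlation, or 0.00631 without control replicate 2).

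Genes of MHC class I antigen processing were shifted upwards as a list (median 0.26, adjusted p = 0.0033, adjusted p = 0.504 with an estimated correlation), and 2 of 13 members rose, the peptide transporter gene TAP1 (2.56, or 3.43 without control replicate 2) and the immunoproteasome gene PSMB8 (1.48). TAP1 was also a member of the IFN-gamma-inducible list. Adjusted over the list alone 4 class I members rose, as with replicate as a block. The median was 0.62 without control replicate 2, with 6 rising over all probe sets, and the adjusted p with an estimated correlation was 0.0408. Genes of Syk kinase and immunoreceptor (ITAM) signalling were also shifted upwards (median 0.18, adjusted p = 0.0253, adjusted p = 0.127 with an estimated correlation), with 2 of 16 past the threshold, the adaptor gene LCP2 (1.29) and the kinase gene LYN (0.98). Adjusted over the list alone, 4 of the 16 rose and 1 fell, the same numbers as with replicate as a block. SYK itself measured 1128 ± 173 in control and 976 ± 256 after IFN-alpha, a difference of -0.23 that did not pass the threshold (adjusted p = 0.598). The class I and Syk lists lost their calls without control replicate 3 or IFN-alpha replicate 3, with the highest adjusted p at 0.0538 for both.

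Members of the JAK-STAT list moved both ways, with 5 of 20 rising and 2 falling, or 7 and 2 adjusted over the list alone, and the list was not shifted (median -0.10, mean 0.42, adjusted p = 0.124). Its adjusted p was 0.0332 without control replicate 2, and adjusted p = 0.087 with an estimated correlation. The tyrosine phosphatase gene PTPN2 (1.79) and IRF9 (1.29), the DNA-binding subunit of the type I interferon transcription complex, rose. IFNGR1, which encodes the ligand-binding chain of the IFN-gamma receptor, fell from 2424 ± 216 to 780 ± 106 (-1.63, adjusted p = 0.000116). Of 20 inflammatory cytokine genes 5 rose and 3 fell, or 5 and 5 adjusted over the list alone, without a shift of the list (median -0.05, mean 0.52, adjusted p = 0.166). The number that fell was 1 without control replicate 2 and 5 with replicate as a block. The monocyte chemoattractant genes CCL7 (3.62) and CCL2 (3.26) rose, CCL2 from 1367 ± 565 to 12350 ± 1903. In the cell cycle list 1 of 14 members passed the threshold, the replication licensing gene MCM7 (-1.36), whose adjusted p was 0.0917 without control replicate 2.

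In all, 373 probe sets rose and 402 fell after IFN-alpha out of 8501 tested, and 298 and 263 of these changed at least 2-fold. The median over all tested probe sets was -0.17, against -0.069 after quantile normalisation and -0.024 with arrays scaled to the same 75th percentile, and the share of called probe sets that rose went from 48.1% to 57.9% and 67.6%. With replicate as a block, 528 rose and 810 fell, and the 775 calls were all kept. The total was 462, 427 and 452 without control replicate 1, control replicate 3 and IFN-alpha replicate 3 in turn.

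The second comparison asked the same of cells cultured with IFN-gamma, by comparing IFN-gamma then IFN-alpha with IFN-gamma. CXCL11 rose from 22.1 ± 23.9 to 6325 ± 2797 (8.15, SE 0.72, adjusted p = 1.22e-05), and RSAD2 from 32.7 ± 18.1 to 7347 ± 1948 (7.68, adjusted p = 2.14e-07). CXCL9 (6.94), CCL8 (6.90), CXCL10 (6.22), IFIT2 (6.12), OASL (6.04), IFIT1 (5.67), IFITM1 (5.39), the exonuclease gene ISG20 (5.29) and SOCS1 (4.78) rose. IDO1, which encodes the tryptophan-degrading enzyme indoleamine 2,3-dioxygenase, rose from 138 ± 55.4 to 4711 ± 1529 (5.04, adjusted p = 5.11e-06). GPR183, an oxysterol receptor gene, fell from 393 ± 65.6 to 22.9 ± 20.4 (-4.09, adjusted p = 0.00162), and the flagellin receptor gene TLR5 fell by 3.12. The second probe set of SOCS1 again did not pass the threshold (0.96, adjusted p = 0.344).

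CXCR4 (-3.37), DUSP7 (-3.32), IRAG2 (-3.24), the sialyltransferase gene ST3GAL6 (-2.49), the TGF-beta receptor gene TGFBR2 (-2.46) and IFNGR1 (-2.31) also fell in cells cultured with IFN-gamma, though the second probe set of DUSP7 did not pass the threshold (-1.11, adjusted p = 0.317). FRAT2 (-2.71, adjusted p = 0.0143), the transcription factor gene MAF (-2.61, adjusted p = 0.0147), IRAK3 (-2.44, adjusted p = 0.0245) and the fractalkine receptor gene CX3CR1 (-2.29, adjusted p = 0.0306) fell with calls that single arrays could end. Without IFN-gamma replicate 3 their adjusted p was 0.0509, 0.0662, 0.108 and 0.113. For CX3CR1, leaving out IFN-gamma replicate 1 or 2 or IFN-gamma then IFN-alpha replicate 2 or 3 also ended the call, with an adjusted p of up to 0.116. The same held for FRAT2 and MAF without IFN-gamma replicate 1 (0.052 and 0.058) and for MAF without IFN-gamma then IFN-alpha replicate 2 (0.0524). For IRAK3 it held without IFN-gamma replicate 2 (0.0772) or IFN-gamma then IFN-alpha replicate 1 (0.0849) or 3 (0.0848).

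In the antiviral list 27 of 33 members rose and 0 fell after IFN-alpha in these cells, or 30 adjusted over the list alone, and the list was shifted upwards (median 2.66, adjusted p = 2.32e-51). MX1 reached 8871 ± 1342 (4.44) and ISG15 reached 13710 ± 2815 (4.01). Of the IFN-gamma-inducible genes 8 of 21 rose, or 11 with 1 falling adjusted over the list alone (median 1.59, adjusted p = 4.98e-14, adjusted p = 0.277 with an estimated correlation), while IRF1 went from 1202 ± 188 to 1473 ± 166, a difference of 0.30 that did not pass the threshold (adjusted p = 0.788). Of 17 apoptosis genes 5 rose, or 10 with 1 falling adjusted over the list alone, including CASP5 (3.20), XAF1 (2.43) and FAS (1.97), and the list was shifted upwards (median 0.95, adjusted p = 2.66e-07, adjusted p = 0.0989 with an estimated correlation). Without control replicate 2, which enters this comparison only through the spread, 13 IFN-gamma-inducible and 8 apoptosis genes rose, and with replicate as a block 11 and 10. The adjusted p with an estimated correlation was then 0.0575 and 0.013 without that array.

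Inflammatory cytokine genes were shifted upwards in the IFN-gamma cultures (median 0.52, adjusted p = 0.00139, adjusted p = 0.45 with an estimated correlation). Of 20 members 5 rose, or 6 with 2 falling adjusted over the list alone, among them CCL8, the interleukin-1 receptor antagonist gene IL1RN (3.95), CCL2 (3.32), CCL7 (2.70) and TNF (2.03, from 199 ± 44.7 to 854 ± 337, or 0.71 with an adjusted p of 0.0833 in its second probe set). That list lost its call without IFN-gamma then IFN-alpha replicate 2 (adjusted p = 0.087). The class I processing list was shifted by a median of 0.15 with 0 of 13 members past the threshold in limma (adjusted p = 0.0449, adjusted p = 0.603 with an estimated correlation), and its call held in 13 of the 22 alternatives, among which fry is counted. It was lost in 4 of the leave-one-array-out fits, at an adjusted p of up to 0.159, and with quantile normalisation, 75th percentile scaling and the stricter filter. In fry, which tests a list against no change and not against the other genes, its adjusted p was 0.653. Monocyte genes (median -0.54) and cell cycle genes (-0.43) were lower in fry (adjusted p = 0.0103 for both) but not against the other genes (adjusted p = 0.332 for both by camera), where the median over all tested probe sets was itself below 0. SYK measured 1243 ± 266 before and 808 ± 73.2 after IFN-alpha, a difference of -0.60 (adjusted p = 0.141, or 0.0338 with replicate as a block). The actin 3'/5' signal ratio, a sign of RNA quality, was 1.29 ± 0.13 in control, 1.47 ± 0.24 after IFN-alpha, 1.17 ± 0.17 with IFN-gamma and 1.30 ± 0.15 with both. The GAPDH ratio was 1.37 ± 0.12 in control, 1.32 ± 0.22 after IFN-alpha, 1.16 ± 0.07 with IFN-gamma and 1.38 ± 0.1 with both.

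After IFN-gamma culture, 342 probe sets rose and 329 fell with IFN-alpha. The median over all tested probe sets was -0.215, against -0.079 after quantile normalisation and -0.041 with 75th percentile scaling, and the share of calls that rose was 51.0%, 64.0% and 69.9%. With replicate as a block, 497 rose and 656 fell. The total of 671 was 335 without IFN-gamma replicate 3, 432 without IFN-gamma then IFN-alpha replicate 1, and 429 without its replicate 2 or its replicate 3.

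The third comparison asked what the culture with IFN-gamma changed by itself. With all arrays no gene passed the threshold, and 1 control array stood apart. The immunoproteasome gene PSMB9 measured 534 and 434 in control replicates 1 and 3, but 4070 in control replicate 2, where the IFN-gamma arrays measured 3954 ± 606. The adhesion glycoprotein gene THBS1 measured 3108 and 1823 in control replicates 1 and 3, 134 in control replicate 2, and 214 ± 142 in the IFN-gamma group. The complement inhibitor gene SERPING1 measured 413, 5647 and 508 in control replicates 1, 2 and 3, against 5055 ± 2298 with IFN-gamma.

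**Figure D2:**
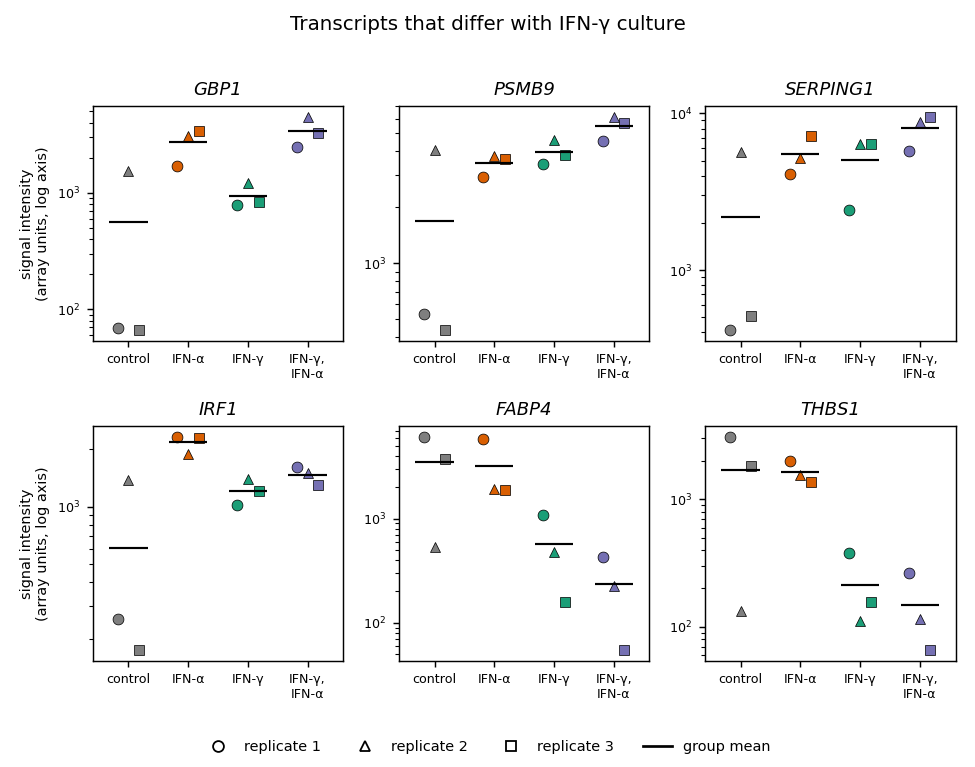
Signal of 6 genes on each of the 12 arrays (log axis), by group, with a bar at each group mean. In GBP1, PSMB9, SERPING1 and IRF1 the array of control replicate 2 lies with the IFN-gamma arrays, above the other control arrays, and in FABP4 and THBS1 it lies below them.

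Of 8501 probe sets, 0 passed the threshold in limma for IFN-gamma minus control with all arrays, and 386 had an unadjusted p under 0.05. The genes with the smallest p included IRF9 (691 ± 194 in control and 1313 ± 105 with IFN-gamma, 0.95), the coagulation inhibitor gene TFPI (253 ± 160 and 36.0 ± 12.5, -2.36), FLRT2 (-2.74), the adhesion receptor gene ADGRE1 (-1.03) and the chromatin organiser gene SATB1 (-0.76), each with an adjusted p of 0.998. MEIS3P1 (1.70), B4GALT5 (1.68), SERINC1 (-0.65) and CEP350 (-0.76) were also among the 10 smallest, of which 9 are named. The blocked fit also made 0 calls. The control SD of an affected gene such as PSMB9 was 2071 on a mean of 1680.

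Without control replicate 2, 55 probe sets were higher and 24 lower with IFN-gamma. GBP1, a guanylate-binding protein gene of cell-autonomous immunity, was higher by 3.65 (adjusted p = 0.000108), and its relative GBP2 by 3.25. LGALS3BP (4.27), CXCL10 (3.47), SERPING1 (3.31), PLAAT4 (3.18), SCO2 (3.03), VAMP5 (3.02), PSMB9 (3.01), TNFSF10 (2.96), the peptide transporter gene TAP2 (2.92) and GCH1 (2.66), which encodes the first enzyme of tetrahydrobiopterin synthesis, were the others with the largest increases. The largest decreases were those of the heparan sulfate proteoglycan gene SDC2 (-3.69), THBS1 (-3.63), FLRT2 (-3.23), TFPI (-3.11), the protease gene HTRA1 (-2.80), PALLD (-2.62), CREM (-2.11) and the lipid droplet gene PLIN2 (-1.79). PC (-1.71), ITGAE (-1.61), OLFML2B (-1.59) and RPS6KA2 (-1.53) followed. Other probe sets of VAMP5 (-0.267) and THBS1 (-0.24) did not pass the threshold (adjusted p = 0.999 for both), while another of THBS1 did (-2.243). With replicate as a block as well, 116 were higher and 59 lower. Leaving out each array was fixed in advance as an alternative, while singling out this one and naming its genes followed from its values. Its values resemble those of the IFN-gamma arrays, so the calls made without it are partly fixed by that choice.

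As lists, MHC class I processing (median 0.89, adjusted p = 4.87e-13), IFN-gamma-inducible genes (0.76, adjusted p = 1.79e-10), antiviral genes (0.45, adjusted p = 2.93e-10) and MHC class II genes (0.42, adjusted p = 8.47e-07) were shifted upwards with IFN-gamma on all arrays. Apoptosis (0.20, adjusted p = 0.00285), Syk signalling (0.17, adjusted p = 0.0176) and monocyte genes (0.35, adjusted p = 0.0363) were shifted upwards too, and macrophage differentiation genes downwards (-0.28, adjusted p = 0.00285). In none of these 8 lists did a member pass the threshold over all probe sets, and 6 of 13 class I genes were higher adjusted over the list alone. With an estimated correlation all 8 calls were lost, at an adjusted p of 0.148 for class I, 0.216 for IFN-gamma-inducible genes, 0.208 for antiviral genes, 0.149 for class II, 0.216 for apoptosis, 0.149 for Syk signalling, 0.167 for monocyte genes and 0.27 for macrophage differentiation. The class II call had an adjusted p of 0.0263 in that test with replicate as a block.

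Without control replicate 2, 10 of 21 IFN-gamma-inducible genes, 7 of 13 class I genes and 4 of 33 antiviral genes were higher, or 12, 9 and 14 adjusted over the list alone. The list medians were then 1.42, 1.31 and 0.83, with an adjusted p of 0.0203, 0.00865 and 0.0474 with an estimated correlation. Control replicate 2 was singled out because it carried the profile of IFN-gamma culture. Leaving it out widens the difference for such genes, so the shifts without it are partly fixed by that choice and are no independent test. Macrophage differentiation genes stood at -0.62 without that array (adjusted p = 0.0116 with an estimated correlation) and the apoptosis list passed that test as well (0.0203), with FABP4, a fatty acid-binding protein gene of macrophages, at 3465 ± 2809 in all controls and 572 ± 469 with IFN-gamma. The monocyte list lost its call without control replicate 2 (adjusted p = 0.158), and also without control replicate 1, IFN-gamma replicate 1 or IFN-gamma replicate 3. The Syk list lost its call without control replicate 1 (adjusted p = 0.0507). Apoptosis and macrophage differentiation lost theirs without control replicate 1 or 3, with an adjusted p of up to 0.0957 for both, and the latter also without IFN-gamma replicate 3.

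**Figure D3:**
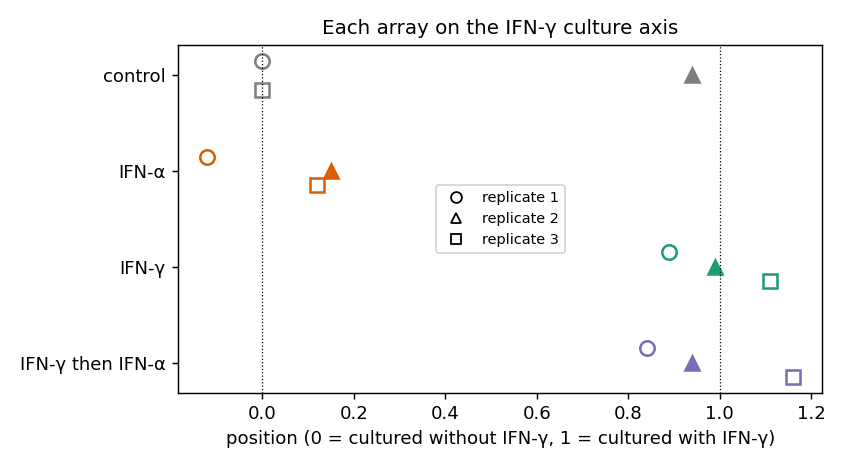
Position of each array between cells cultured without IFN-gamma (0) and with it (1), drawn from replicates 1 and 3 on 2 axes, 1 without and 1 with IFN-alpha; filled symbols are the replicate 2 arrays, which were not used to draw an axis. Control replicate 2 lies at 0.94 and IFN-gamma replicate 2 at 0.99, while IFN-alpha replicate 2 lies at 0.15.

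The fourth comparison set cells cultured with and without IFN-gamma against each other when both had IFN-alpha, and it used none of the control arrays in its means. IDO1 was higher by 2.92 in the IFN-gamma then IFN-alpha group, at 4711 ± 1529 against 636 ± 310 in the IFN-alpha group (SE 0.39, adjusted p = 0.0301). ZFP36L2, an RNA-binding protein gene of mRNA decay, was higher by 1.80, at 3580 ± 713 against a mean of 1049 (adjusted p = 0.0301). A second probe set of ZFP36L2 (1.29) and 1 of 2 probe sets of the pseudokinase gene TRIB2 (2.95), both at an adjusted p of 0.0451, made up the 4 calls; TRIB2 was named after its values were seen. The smallest p beyond these belonged to the Notch effector gene RBPJ (-1.18) and ZMIZ1 (-1.50), both with an adjusted p of 0.0589 as for RIPOR2 (2.80), to TFPI (-2.86) and OLFML2B (-2.27), both at 0.0742, and to SLC7A7 (0.91) and STAT4 (-1.50), both at 0.0824.

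With replicate as a block, which compares arrays of the same set, the IFN-gamma then IFN-alpha group was higher than the IFN-alpha group in 54 probe sets and lower in 71. FABP4 (-3.91), THBS1 (-3.60), SDC2 (-3.52), PPBP (-3.39), the fibronectin gene FN1 (-3.10), TFPI (-2.86), GPR183 (-2.70), SELENOP (-2.61), DAB2 (-2.28), OLFML2B (-2.27), MAF (-2.23) and GPX3 (-2.10) had the largest decreases. FABP4 stood at 238 ± 189 against 3193 ± 2233 (adjusted p = 0.0141). IDO1, RIPOR2, the chemokine receptor gene CCR2 (2.71), SLC6A12 (2.30), CXCL11 (2.01), SERPINA1 (1.98), the calprotectin gene S100A8 (1.89), SPRR2D (1.82), the DNA sensor gene AIM2 (1.82), ZFP36L2, TRIB2 (1.78 in its other probe set) and IL2RG (1.63) had the largest increases. These were chosen by the same rule, after the values of that fit were seen. Other probe sets of THBS1, FN1, RIPOR2 and CCR2 changed in the same direction but did not pass the threshold there, at an adjusted p of 0.0525 to 0.504. PPBP is a platelet gene, and the platelet list stood at a median of -0.02 in this comparison (adjusted p = 0.926) and at -0.97 for IFN-gamma minus control (adjusted p = 0.194).

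Macrophage differentiation genes were shifted downwards in this comparison (median -0.50, adjusted p = 5.33e-06, adjusted p = 0.365 with an estimated correlation, or 0.0131 without control replicate 2). None of the 21 members passed the threshold over all probe sets, 9 were lower adjusted over the list alone and 6 were lower with replicate as a block. MHC class I (median 0.64, adjusted p = 1.42e-05, adjusted p = 0.365 with an estimated correlation), MHC class II (0.54, adjusted p = 0.000161, adjusted p = 0.365 with an estimated correlation) and IFN-gamma-inducible genes (0.38, adjusted p = 0.00111, adjusted p = 0.956 with an estimated correlation) were shifted upwards. In the class II list 3 of 13 members were higher adjusted over the list alone, and with replicate as a block 5 were higher and 1 lower, the higher ones including the invariant chain gene CD74 at 9158 ± 2844 against 5092 ± 1834 (0.88, blocked adjusted p = 0.0141). IDO1 was the single IFN-gamma-inducible gene past the threshold. The antiviral list stood at a median of 0.02 (adjusted p = 0.379), with IFIT1 at 11900 ± 1542 with IFN-gamma and 11940 ± 2930 without it. Without IFN-alpha replicate 1 the IFN-gamma-inducible and class II lists lost their calls (adjusted p = 0.133 and 0.0582).

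The number of calls in this comparison depended on single arrays. It was 38 without control replicate 2, and 256 with replicate as a block in addition. It was 0 without control replicate 1, IFN-alpha replicate 1, IFN-gamma replicate 3, or IFN-gamma then IFN-alpha replicate 2 or 3, and 2 without IFN-gamma replicate 1 or 2, IFN-alpha replicate 2 or 3, or IFN-gamma then IFN-alpha replicate 1. IDO1 lost its call in 6 of these fits, with the highest adjusted p at 0.148 without IFN-alpha replicate 1, and ZFP36L2 in 7, with its highest at 0.148 without the same array, and also without an intensity trend (0.0658).

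**Figure D4:**
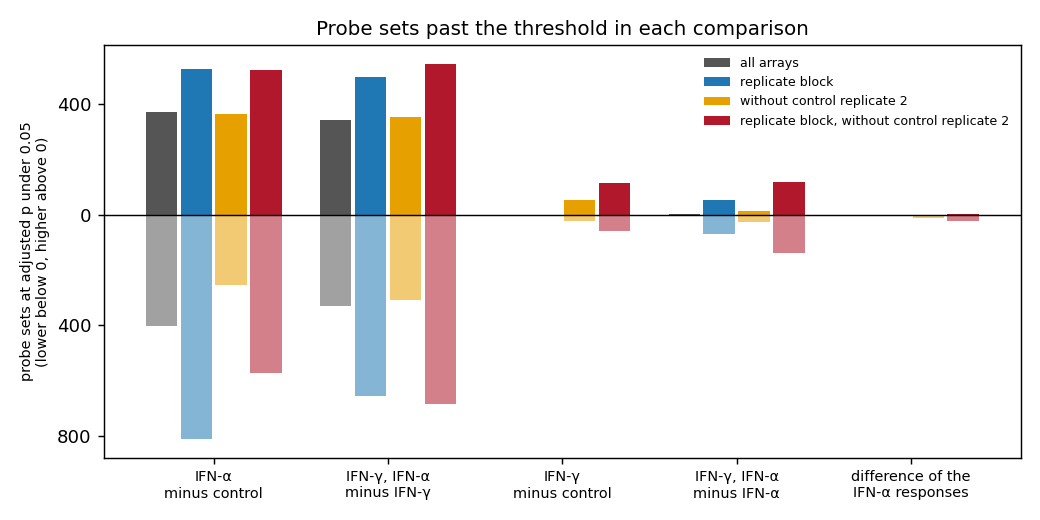
Number of probe sets past the threshold in each of the 5 comparisons, higher and lower, with all arrays, with replicate as a block, without control replicate 2, and with both. For IFN-alpha minus control the totals are 775, 1338, 618 and 1092, and for IFN-gamma minus control they are 0, 0, 79 and 175.

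The last comparison tested whether culture with IFN-gamma altered the response to IFN-alpha, as the response after IFN-gamma culture minus the response without it. IDO1 had a response larger by 2.90 (SE 0.55), at 5.04 after IFN-gamma culture against 2.14 without it, and ZFP36L2 had one larger by 1.52 (SE 0.35), at -0.08 against -1.60. Neither passed the threshold (adjusted p = 1 for both, and 0.0793 for IDO1 and 0.131 for ZFP36L2 with replicate as a block). Of the genes chosen in advance to be given in any case, the response differed by -0.52 for MX1 (SE 0.49), by -0.57 for ISG15 (SE 0.36), by -1.28 for SOCS1 (SE 0.64), by -1.97 for CXCL10 (SE 1.26), by 1.58 for CXCL9 (SE 0.82), by -2.13 for IRF1 (SE 0.75) and by -0.36 for SYK (SE 0.32). Without control replicate 2 these were -0.94 for MX1, -0.82 for ISG15, -1.87 for SOCS1, -3.39 for CXCL10, 1.01 for CXCL9, -3.02 for IRF1 and -0.30 for SYK.

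Across the 8501 probe sets 0 passed the threshold in limma for this difference, and 248 had an unadjusted p under 0.05. The other genes with the smallest p were FAM53B (1.53), MEIS3P1 (-2.05), RIPOR2 (2.67), TCF7L2 (2.41), the defensin gene DEFB1 (1.59), CNTN1 (-1.30), ADGRE1 (1.36) and IRF9 (-1.08), each at an adjusted p of 1. Of 20 gene lists 1 passed the threshold, the antiviral genes with a smaller response after IFN-gamma culture (median -0.33, adjusted p = 0.00256, adjusted p = 0.764 with an estimated correlation) and 0 of 33 members past the threshold. That call was lost without control replicate 3, IFN-alpha replicate 3, or IFN-gamma then IFN-alpha replicate 1, with an adjusted p of up to 0.457. Without control replicate 2, the response was smaller in 10 probe sets, among them IRF1 (-3.02), GBP1 (-3.30), GBP2 (-2.81), IFIT3 (-2.36), PSMB9 (-2.35), VAMP5 (-2.02) and TAP1 (-1.84), named after their values were seen. The IFN-gamma-inducible list then stood at -1.26 with 6 of 21 members smaller (adjusted p = 1.07e-17, adjusted p = 0.065 with an estimated correlation), and the antiviral list at -0.72 (adjusted p = 2.24e-12, adjusted p = 0.1 with an estimated correlation). With all arrays the IFN-gamma-inducible list stood at -0.93 (adjusted p = 0.213 by camera). Control replicate 2 was singled out for its profile of IFN-gamma culture. Leaving it out lowers the control level of such genes, and so raises their response without IFN-gamma. Their smaller responses after IFN-gamma culture are then partly fixed by that choice and are no independent test. Class I (adjusted p = 5.07e-09), apoptosis (0.000829) and JAK-STAT genes (0.00157) also had smaller responses as lists without that array, each at an adjusted p of 0.065 with an estimated correlation. Macrophage differentiation genes did with replicate as a block on all arrays (adjusted p = 0.03, adjusted p = 0.709 with an estimated correlation).

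The 2 IFN-alpha responses, which share no arrays in their means, had 256 probe sets higher in both and 199 lower in both. Independent calls would share 15.0 and 15.6. Both responses use the same estimate of the spread for each probe set and the same 3 sets, so their calls are not fully independent. Of the 373 that rose without IFN-gamma, 366 had a change in the same direction after IFN-gamma culture, with medians of 1.58 and 1.33, and of the 402 that fell 399 did, with medians of -1.15 and -0.94. These probe sets were chosen for passing the threshold without IFN-gamma, which favours large changes there. The smaller medians after IFN-gamma culture therefore do not show a weaker response. Across all tested probe sets, which are not independent replicates, the changes correlated with Pearson's r = 0.76 and Spearman's rho = 0.58. With replicate as a block 746 probe sets were called in the same direction in both, and 268 without IFN-gamma replicate 3. With all arrays IFN-gamma minus control had 0 calls, so none could be shared with IFN-alpha minus control. Without control replicate 2 the 2 comparisons shared 43 that were higher and 2 that were lower, though both use the same control arrays and so their calls are not independent.

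The lists of complement and phagocytosis, sterol and lipid, cell cycle and ribosomal protein genes did not pass the threshold by camera in any of the 5 comparisons with all arrays, although the ribosomal list did for IFN-gamma minus control with replicate as a block (adjusted p = 0.0276, adjusted p = 0.546 with an estimated correlation). CFB, a complement factor gene (1.84, adjusted p = 0.0219), and the sterol sensor gene INSIG1 (1.72, adjusted p = 0.0301) rose with IFN-alpha after IFN-gamma culture, and the cholesterol transporter gene ABCG1 fell (-1.47, adjusted p = 0.0371). Markers of T, NK and B cells, platelets, neutrophils and dendritic cells did not pass it as lists by camera or fry with all arrays. The smallest adjusted p among them for IFN-alpha minus control was 0.741 by camera and 0.649 by fry. With the block and without control replicate 2, the platelet list (adjusted p = 0.0273) and the complement list (0.0309) passed it for IFN-gamma minus control, and the complement list (0.028) for IFN-gamma then IFN-alpha minus IFN-alpha; these were not tested with an estimated correlation. The erythroid list had 2 named members, too few for a test, with a median signal of 54.2 to 430 over the arrays.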

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

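The tests of explanations for the antiviral genes and for control replicate 2, and the test on 3'/5' ratios, were chosen only after the result was seen; the antiviral list and its test, leaving out each array, the test on the scale of the arrays and the regrouping of arrays were chosen before.

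The smaller rise of the antiviral genes after IFN-gamma culture was singled out because a test of the difference between the 2 cultures passed the threshold (median log2 difference -0.33). In it, 27 of 33 members had a smaller rise, and before IFN-alpha the list stood higher with IFN-gamma than in control by a median of 0.45 (0.83 without control replicate 2). A limit at the upper range of the arrays was argued against, since the 10 members under a signal of 2000 in every group had a median of -0.72 (-0.71 without control replicate 2). A lower level reached with IFN-alpha stays open: the median of IFN-gamma then IFN-alpha minus IFN-alpha was 0.02 with 16 of 33 members lower, but -0.13 with 7 of 10 lower among those under 2000. Chance stays open too. The regroupings of the arrays, which ignored the sets and so include differences between sets, counted any shifted list and not the antiviral list itself. Of 100, 93 gave at least the real count of 1 list, with 12 as the highest other. They therefore cannot decide on the antiviral list.

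The second pattern was the array of control replicate 2, which carried the profile of IFN-gamma culture, at 0.94 on an axis from control (0) to IFN-gamma (1). An exchange of its label with IFN-gamma replicate 2 was argued against by the position of the latter at 0.99, and exposure of the whole set to IFN-gamma by that of IFN-alpha replicate 2, at 0.15 on the matching axis. An array from another set was argued against by its position of 0.74 on an axis for set 2, where the other arrays of that set lay at 0.94 to 1.04 and those of other sets at -0.07 to 0.14. A sample of the same set cultured with IFN-gamma and carrying this label, or IFN-gamma reaching that culture, stays open, and no biological explanation was tested. The array was kept in its labelled group, and the results that moved most are given with and without it.

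The last pattern was a lower median signal on arrays of cells given IFN-alpha, at 64.8 ± 12.3 and 59.6 ± 0.82 (n = 3) against 73.3 ± 2.39 in control and 73.4 ± 5.23 with IFN-gamma. IFN-alpha replicate 2 did not share it, with the highest median of all arrays (76.8, against 72.6 in control replicate 2). A single factor per array cannot be told apart from a change in the cells, because the brightest and dimmest probe sets differed in their median change by 0.03 without IFN-gamma but by 0.137 with it. Poorer RNA cannot be told apart either, since 10 of 12 differences of the 3'/5' ratios of actin and GAPDH were higher after IFN-alpha, short of all 12. The others were those of IFN-alpha replicate 2, at 1.19 against 1.24 in control replicate 2 for actin and 1.1 against 1.5 for GAPDH. That array is also the one without the lower median, so the shortfall does not argue against poorer RNA. The size of the shift did not follow the ratios in sets 1 and 3, however. Without IFN-gamma, the median change over tested probe sets was -0.129 in set 1 and -0.318 in set 3. The actin ratio went from 1.19 to 1.63 in set 1 and from 1.43 to 1.59 in set 3. The GAPDH ratio went from 1.34 to 1.54 and from 1.27 to 1.32, so poorer RNA stays open.

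Other regroupings of the same arrays, which ignored the sets, were counted for each comparison. With 10 splits of 3 against 3, a share below 0.1 cannot be reached, so they are too few to decide, and only the values are given. For IFN-alpha minus control the real split gave 775 probe sets and the highest other 0 (1 split as large), and 5 lists against 9 (6 splits as large). After IFN-gamma culture it gave 671 against 0 (1) and 5 lists against 6 (4). For IFN-gamma minus control it gave 0 against 25 (10) and 8 lists against 10 (2), where the split with 25 and 10 put control replicate 2 with IFN-gamma replicates 2 and 3. For IFN-gamma then IFN-alpha minus IFN-alpha it gave 4 against 0 (1) and 4 lists against 6 (5). For the difference of the responses 100 of 100 splits gave at least the real count of 0 probe sets, with 3 as the highest other.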

How the results depend on the processing

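The block with control replicate 2 left out was chosen only after the data were seen; the other alternatives were fixed before the data were examined. Of 1098 alternative values for the 50 named-gene results past the threshold, 1047 stayed past it in the same direction, 51 in 9 results did not, and 0 reversed; 45 of 602 values of the 28 others passed it. The antiviral list held in all 22 alternatives in both IFN-alpha comparisons. Other list calls were lost, besides with an estimated correlation and single arrays, as follows: with quantile normalisation, class I in both IFN-alpha comparisons, Syk signalling for IFN-alpha minus control and IFN-gamma minus control, and monocyte genes for the latter; with the stricter filter, class I after IFN-gamma culture and monocyte genes; with 75th percentile scaling, class I after IFN-gamma culture; and with the block without control replicate 2, monocyte genes. In fry, which tests a list against no change and not against the other genes, class I in both IFN-alpha comparisons, inflammatory cytokines after IFN-gamma culture and every list of the other comparisons did not pass, while monocyte and cell cycle genes did after IFN-gamma culture, downwards (adjusted p = 0.0103 for both). For IFN-alpha minus control (775 probe sets), the count was 1338 with the block, 438 with only the compared groups in the fit (fewer samples), and 427 to 735 leaving out 1 array; its 5 lists became 3 with quantile normalisation, 1 with an estimated correlation, and 3 to 6. After IFN-gamma culture (671), it was 1153 with the block, 1230 with the block without control replicate 2, and 335 to 744 leaving out 1 array; its 5 lists became 1 with an estimated correlation and 3 to 5. For IFN-gamma minus control (0), it was 0 to 79 leaving out 1 array and 175 with the block without control replicate 2; its 8 lists became 0 with an estimated correlation, 0 with fry, and 5 to 10. For IFN-gamma then IFN-alpha minus IFN-alpha (4), it was 2 with a pseudocount of 1, 125 with the block, 20 with only the compared groups, 2 with 1 probe set per gene (fewer tested), 0 to 38 leaving out 1 array, and 256 with the block without control replicate 2. Its 4 lists became 0 with an estimated correlation, 0 with fry, and 2 to 6. For the difference of the responses (0), it was 0 to 10 leaving out 1 array and 23 with the block without control replicate 2. Its 1 list became 2 with quantile normalisation, 4 with the stricter filter, 2 with the block, 0 with an estimated correlation, 0 with fry, 0 to 5, and 6 with the block without control replicate 2. Calls shared by IFN-alpha and IFN-gamma (0, as IFN-gamma had none) numbered 0 to 45 leaving out 1 array and 88 with the block without control replicate 2. The probe sets past the threshold in the same direction in both IFN-alpha responses (455) numbered 746 with the block, 268 to 434 leaving out 1 array, and 727 with the block without control replicate 2. Where no cause is given, the cause was not tested. Signals near the pseudocount of 6 limit what dim probe sets show.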

Other observations

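The lists of chemoattractant receptors and of Toll-like receptor pathway members were chosen only after the result was seen. The list of immediate-early transcripts was also made after the main results, though before its values as a list were seen. Its member MCL1 had already been tested in the apoptosis list. Among immediate-early genes, the dual-specificity phosphatase gene DUSP5 rose with IFN-alpha from 107 ± 113 to 1041 ± 182 (n = 3, 3.80, adjusted p = 0.00134) and the stress-response factor gene ATF3 from 112 ± 38.6 to 772 ± 232 (2.72). KLF6 (1.53), MCL1 (1.23), ZFP36 (1.08) and IER2 (0.82) also rose, while FOS (-2.08), SGK1 (-1.76) and DUSP1 (-1.71) fell. After IFN-gamma culture DUSP5 (2.85), ATF3 (2.30), KLF6 (1.84), IER2 (1.43), ZFP36 (1.00) and MCL1 (0.88) rose, and TRIB1 (-1.98), FOS (-1.78) and EGR1 (-1.55) fell. Of the receptors, CCR1 (1.04), CMKLR1 (0.83) and FPR2 (adjusted p = 0.0087) rose without IFN-gamma and CCR1 (0.95), CCRL2 (1.47) and CMKLR1 (1.04) after it. In the Toll-like receptor pathway, the adaptor genes MYD88 (1.59) and TICAM1 (0.74) rose without IFN-gamma and MYD88 (1.14) after it.

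The falls of CXCR4, TLR5, IRAK3, DUSP7 and DUSP10 prompted the hypothesis that IFN-alpha lowers whole groups of such transcripts. The lists of receptors and of the Toll-like receptor pathway left out the members already seen to fall. The medians for IFN-alpha minus control were 0.08 for immediate-early transcripts, 0.28 for chemoattractant receptors and 0.11 for the Toll-like receptor pathway, against -0.19 over all tested genes. After IFN-gamma culture they were 0.21, -0.02 and -0.13, against -0.22. Lower levels of these groups were not seen, but they stay open: members moved both ways, and 2 of the lists left out genes that fell. Adjusted over these 6 tests, camera placed them above the other genes at an adjusted p of 0.0429, 0.0363 and 0.0411 without IFN-gamma and 0.0325, 0.088 and 0.421 after it. With an estimated correlation the adjusted p was 0.176, 0.122 and 0.122, then 0.14, 0.14 and 0.421, so a higher median alone does not exclude lower levels.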
